A study of Sus scrofa with 9 samples.

How the data were processed

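RNA was measured in 9 heart samples from miniature pigs (Sus scrofa), 3 given vehicle, 3 given doxorubicin and 3 given doxorubicin plus formononetin. Per the labels' protocols, total RNA was isolated with a silica-column kit (RNeasy), 2 µg entered each library, and libraries were made with a SMARTER kit for messenger RNA. The dose, the time of treatment, the part of the heart that was sampled and the age and sex of the animals are not given in the sources used here. The authors deposited one table of counts per gene for all 9 libraries, with whole numbers that sum to a different total in each library. The aligner, the counting program and its handling of strand and of reads shared between genes are not given in the sources used here. The deposited counts of genes that share reads are therefore uncertain. This concerns the swine leukocyte antigen (SLA) genes and the overlapping mitochondrially encoded genes ATP8 and ATP6 in particular. The deposited gene lengths, which the authors gave for each gene, were used in 1 check only.

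The table holds 30942 genes, of which 23009 had at least 1 count. NCBI gene identifiers matched the RefSeq annotation of the pig assembly Sscrofa11.1 for 30335 genes, all with the same symbol and the same start position, so coordinates below are from that assembly. Another 583 entries are unannotated loci added by the authors and are not described by name. No reference genome was used here, and no check of GC content was made. Samples were assigned to groups from the treatment named in their labels, and replicate numbers from their titles.

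Counts were analysed in R (version 4.3.3) with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr (minimum count 10), which left 14846 genes and set aside 16096. Library sizes were scaled by TMM. A negative binomial model with 1 mean per group was fitted to all 9 libraries together, and each pair of groups was compared by the edgeR quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. All adjusted p-values of genes below are from this test unless another is named. Fold changes are log2 values with approximate standard errors. These were derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. Levels are TMM-scaled CPM (library counts scaled to 1e+06), given as mean ± SD with n = 3 libraries in each group. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

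Gene lists for the heart, for doxorubicin and formononetin, and for the other cell types a heart sample can hold were fixed before the data were examined. There were 46 lists with 1209 entries, of which 1160 matched a gene by symbol or listed synonym. Lists with at least 5 tested members (43 lists) were tested with camera from limma on log2 CPM with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with camera using a correlation estimated from the residuals, and with fry, whose directional p-value asks whether the members move, on balance, one way. For each list the calls are given over all genes tested and adjusted over the list alone. List names are those fixed beforehand: they describe where the members are known from, and several members belong to more than 1 list.

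The genes named in the text follow a rule fixed before the data were examined. For each comparison it took the 8 genes that rose and the 8 that fell by the largest log2 fold change among those past an adjusted p of 0.05 whose groups did not overlap and whose mean was at least 5 CPM in the higher group. It added up to 4 members of each list, those with the smallest p, and always named ESRRA, ESRRG, PPARGC1A, NPPA, NPPB, CDKN1A and TOP2B. Members named only to complete a count of 5 or fewer in a list, and the few other genes outside this rule, were chosen after their values were seen, and most of these were not followed through the alternatives. For genes with a fold in the text and at most 3 counts per library on average in a group, the fold is given against a floor of 3 counts per library, or as a ratio of summed counts with a 95% exact interval. Floors and intervals cover counting error only, since the reads carry no molecular identifiers in the deposited table.

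Total counts ranged from 16291952 to 17549359 per library. At this depth, the procedure was tested on simulated counts of changed and unchanged genes drawn from the means and library sizes of the real samples. For doxorubicin against vehicle it recovered 10.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 78.8% of those changed 4-fold, with 3.1% of calls false. For doxorubicin plus formononetin against doxorubicin the values were 10.4%, 55.2% and 80.3%, with 5.8% false. For doxorubicin plus formononetin against vehicle they were 17.9%, 59.7% and 89.4%, with 5.1% false. Each simulation changed 67, 67 and 66 genes by these folds, while 4947, 4173 and 262 genes were called in the real comparisons. With more genes changed the p-value cut-off is less strict, so the shares for the first 2 comparisons may be too low. Called genes there had median absolute log2 fold changes of 0.72 and 0.73, so changes below 2-fold were called as well. How many were missed is not known. No pair of replicates was close enough to be 1 library deposited more than once: the chi-square per degree of freedom of their counts lay between 10.2 and 54.4.

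A gene was counted as reversed when it was called with doxorubicin against vehicle and called in the opposite direction when formononetin was added to doxorubicin. The doxorubicin libraries enter both comparisons, so the counts were set beside 20 simulated datasets in which formononetin changed nothing. Alternatives covered the scaling (DESeq2 size factors, upper quartile, library totals only), the filter, the tool (DESeq2 1.42.0, limma-voom), the samples in the fit, the replicate number as a block, the adjusted p threshold (0.1 and 0.01), a minimum fold of 1.5 tested with glmTreat, library sizes without mitochondrially encoded genes, and leaving out each library in turn. Chosen after the data were seen were a correction for gene length, matching of 13 further list entries by their description, and the estimated correlation over 8 libraries. The share of counts from mitochondrially encoded genes and the number of genes detected were compared by two-sided exact permutation tests. With 3 libraries against 3, such a test gives no p below 0.1.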

Results

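Messenger RNA was profiled in hearts of wild-type miniature pigs in 3 groups of 3 libraries: vehicle, doxorubicin, and doxorubicin plus formononetin. Doxorubicin is an anthracycline, a chemotherapy drug that poisons topoisomerase II, intercalates in DNA and is known for its toxicity to heart muscle. Formononetin is an isoflavone, a plant compound of the phytoestrogen class. The series concerns whether activating the transcriptional pathway of estrogen-related receptor alpha (ERR-alpha, encoded by ESRRA) eases anthracycline cardiotoxicity through mitochondrial metabolism. Library totals were 16935307, 16427266 and 17344459 counts with vehicle, 17040712, 16291952 and 16534811 with doxorubicin, and 17549359, 16619136 and 16872805 with doxorubicin plus formononetin.

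The libraries held many mitochondrial transcripts, with COX1 alone taking 6.13% to 9.25% of counts. Mitochondrially encoded genes made up 21.06% ± 0.30 (SD, n = 3) of counts with vehicle, 23.69% ± 0.60 with doxorubicin and 25.66% ± 3.42 with doxorubicin plus formononetin. The exact permutation p for these shares was 0.1 for doxorubicin against vehicle, 0.4 for doxorubicin plus formononetin against doxorubicin and 0.1 for doxorubicin plus formononetin against vehicle. An exact p of 0.1 is the smallest that 3 against 3 libraries can give. The second doxorubicin plus formononetin library stood apart. In it 14766 genes had at least 1 count, against 18107 to 19304 in the other 8. At 0 in it were 24 of 11102 genes that had at least 2 CPM in all other libraries. The biological coefficient of variation was 12.5% among vehicle libraries, 15.3% among doxorubicin libraries and 24.5% among doxorubicin plus formononetin libraries, or 17.1% without that library. Because all 9 libraries share 1 estimate of the spread, this library weighs on every comparison, and the number of genes called with doxorubicin against vehicle was 6657 without it and 4947 with it.

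In doxorubicin hearts most interferon response genes tested and several cardiac stress genes were higher, and transcripts for ERR-alpha, its partner PPARGC1B and several contractile and calcium-handling proteins were lower. NPPB, which encodes the B-type natriuretic peptide released by strained heart muscle, went from 2.99 ± 3.28 CPM with vehicle to 66.8 ± 1.97 CPM with doxorubicin (n = 3 each). CDKN1A, the p53 target that encodes the cell cycle inhibitor p21, went from 25.4 ± 13.2 to 123 ± 17.2 CPM. ESRRA went from 175 ± 21.6 to 90.9 ± 8.35 CPM, and MYL7, the atrial myosin regulatory light chain, from 710 ± 49.5 to 18.5 ± 7.23 CPM. In all, 4947 of 14846 genes changed, 2421 upward and 2526 downward, and 1456 of them by at least 2-fold. The groups did not overlap for 55.3% of genes tested, where chance gives 10%.

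Among the largest rises with doxorubicin were those of RAB3B, a small GTPase of vesicle release, CHI3L1 (log2 fold change 7.31 ± 1.07 SE), a secreted chitinase-like protein of tissue injury, NPPB (4.46 ± 0.64), the opioid precursor PENK (4.41 ± 0.82), lysozyme LYZ (4.13 ± 0.79), the endothelial proteoglycan ESM1 (3.95 ± 0.75) and the fast skeletal myosin light chain MYL1 (3.90 ± 0.75). RAB3B had 4 counts over the vehicle libraries and 851 with doxorubicin, a ratio of 212 with a 95% interval from 82.7 to 781. The 8 largest falls were in MYL7 (-5.26 ± 0.30), angiotensinogen AGT (-4.96 ± 0.60), the basement membrane protein HMCN2 (-4.76 ± 0.51), the C-type lectin CD209 (-4.67 ± 0.91), the desmosomal protein PPL (-4.55 ± 0.40), the ferritin receptor SCARA5 (-4.16 ± 0.69), the serotonin transporter SLC6A4 (-3.93 ± 0.45) and EMILIN3 (-3.92 ± 0.48). Their adjusted p-values lay between 4.65e-06 (MYL7) and 0.00277 (CD209) by the edgeR quasi-likelihood test. Single libraries moved several of these sizes by more than 1.5 times. Without doxorubicin replicate 1, AGT was at -6.21, HMCN2 at -6.41, SCARA5 at -6.64, SLC6A4 at -4.69 and EMILIN3 at -4.59, and CD209 had 0 counts left against 362 with vehicle, at least 38.5-fold lower. Without doxorubicin replicate 3, CHI3L1 was at 5.93 and PENK at 3.32, and without vehicle replicate 3, NPPB was at 5.90. By limma-voom the calls of CHI3L1 (adjusted p = 0.293), PENK (0.0612) and CD209 (0.052) were lost.

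Interferon-induced genes rose most widely with doxorubicin. Of 43 tested members of the interferon response list, 37 rose, 1 fell and 5 did not pass (38 and 1 adjusted over the list alone), with a median log2 fold change of 1.48. The viral RNA sensor DDX58 rose by 2.68 ± 0.14, the antiviral effector IFIT3 by 2.42 ± 0.19 and IFI44L by 1.62 ± 0.12. The member that fell was the class I antigen SLA-2 (-0.68), whose reads can be shared with other SLA genes. The list was called by camera (adjusted p = 6.46e-17), with adjusted p = 0.582 with an estimated correlation. Macrophage and monocyte genes rose in 11 of 23 cases with 1 fall, FOLR2 (14 and 1 adjusted over the list alone), and AIF1 (1.88 ± 0.24), FCGR3A (1.43 ± 0.17) and the lysosomal protease CTSS (1.30 ± 0.15) were among them. The macrophage list had a camera adjusted p of 2.13e-04, and adjusted p = 0.597 with an estimated correlation. Cell cycle genes rose in 18 of 42 cases with none falling (20 adjusted over the list alone), including thymidylate synthase TYMS (2.64 ± 0.38), the ribonucleotide reductase subunit RRM2 (2.90 ± 0.52) and the mitotic genes CENPF (2.21 ± 0.32) and KIF11 (2.14 ± 0.34). That list had a camera adjusted p of 1.84e-06, and adjusted p = 0.597 with an estimated correlation.

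Some damage and death genes rose as well. Among p53 targets and DNA damage genes 12 of 40 rose and 3 fell (12 and 3 adjusted over the list alone). ZMAT3 rose by 2.21 ± 0.17, CDKN1A by 2.28 ± 0.31, MDM2, which targets p53 for degradation, by 1.04 ± 0.10 and BTG2 by 1.13 ± 0.13. The translesion polymerase POLH (-1.97 ± 0.20), DDB2 and GADD45G fell. The p53 list had a camera adjusted p of 0.0222, and adjusted p = 0.582 with an estimated correlation. Among genes of apoptosis, necroptosis and pyroptosis 12 of 30 rose and BAK1 and BCL2L1 fell (12 and 2 adjusted over the list alone). Rises were seen in the inflammatory caspase CASP1 (3.02 ± 0.26), the pore former DFNA5 (1.32 ± 0.10) and the caspase inhibitors BIRC3 (0.95 ± 0.11) and XIAP (0.83 ± 0.13). Members that promote death and members that block it both rose. The death gene list had a camera adjusted p of 0.0222, and adjusted p = 0.597 with an estimated correlation. Cardiac stress and fetal genes rose in 15 of 30 cases and fell in 2, ACTA1 and MYH7 (15 and 3 adjusted over the list alone). CTGF (1.93 ± 0.14), a matricellular growth factor, and the calcineurin regulator RCAN1 (1.64 ± 0.16) rose with NPPB. The cardiac stress list had a camera adjusted p of 0.00443, and adjusted p = 0.326 with an estimated correlation. NPPA, encoding atrial natriuretic peptide, stood at 14.0 ± 19.1 CPM with doxorubicin and 99.0 ± 99.6 CPM with vehicle and did not pass (adjusted p = 0.0776). TOP2B, the topoisomerase II of non-dividing cells, stood at 149 ± 6.76 and 144 ± 4.34 CPM (adjusted p = 0.759).

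Regulators of mitochondrial gene expression moved apart. ESRRA fell by 0.94 ± 0.12 (adjusted p = 2.11e-04), PPARGC1B by 1.31 ± 0.15 (1.60e-04), and RXRA, the partner of nuclear receptors for fatty acids, by 1.35 ± 0.13 (7.43e-05) on the log2 scale, and the muscle ERR cofactor PERM1 fell as well (4.64e-04). PPARGC1A, the inducible coactivator of ERR-alpha, rose by 0.80 ± 0.10 (2.52e-04). ESRRG rose by 0.43 ± 0.13 (0.0283), a call lost when vehicle replicate 2 or 3 or doxorubicin replicate 1 or 2 was left out (highest adjusted p = 0.125). Of 23 members of the list of ERR and PGC-1 regulators, 4 rose, 6 fell and 13 did not pass (4 and 6 adjusted over the list alone), and PRKAA1 and TFB2M also rose. Among 39 ERR-alpha target genes 14 fell, ESRRA and PERM1 of both lists included, and 4 rose (14 and 5 adjusted over the list alone). The TCA cycle enzyme OGDH fell by 0.72 ± 0.10, and CPT1B, which admits long-chain fatty acids to mitochondria, fell by 0.74 ± 0.11. HADHB and HADHA of the trifunctional protein of fatty acid oxidation, ACADM and MDH1 were the 4 that rose. The camera adjusted p of these lists was 0.658 and 0.0811, so neither was called.

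Lists of the energy pathways themselves were not called by camera with doxorubicin, and members of most of them went both ways. Complex I subunits fell in 13 of 37 cases and rose in 2 (13 and 2 adjusted over the list alone), NDUFA3 (-2.01 ± 0.15) and NDUFA7 (-0.93 ± 0.16) against NDUFS5 (0.83 ± 0.15) and NDUFA5 (camera adjusted p = 0.0579). In complexes II and III, UQCRB fell (-1.23 ± 0.14), alone among the 7 of 14 listed members that matched by symbol (1 adjusted over the list alone, camera adjusted p = 0.822). Among members matched only by their description, and chosen after their values were seen, the complex III subunits LOC100524873 (-0.73 ± 0.14), LOC100156879 (-0.41 ± 0.14) and LOC100525869 (-0.42 ± 0.13) fell and the Rieske subunit LOC100522678 rose (0.49 ± 0.15). In complex IV, where 8 of 13 listed members matched by symbol, 4 of 8 fell (4 adjusted over the list alone, camera adjusted p = 0.366), COX8H (-1.33 ± 0.22), COX7A1, COX6A1 and COX5B. The last 3 lost their calls without doxorubicin replicate 1 or 2 or a vehicle library (highest adjusted p = 0.0661, 0.0731 and 0.0937). Of the complex IV subunits matched only by description, subunit 7B, LOC100516480, rose (0.66 ± 0.19, adjusted p = 0.0216), and it was chosen after its values were seen. ATP synthase subunits fell in 4 of 17 cases (4 adjusted over the list alone, camera adjusted p = 0.545), ATP5G2, ATP5D, ATP5I and ATP5J2. Of 13 mitochondrially encoded subunits, COX2, ND6 and ND2 rose and ATP8 (-2.66 ± 0.33) and COX3 (-0.54 ± 0.11) fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.865). ATP6, which can share reads with ATP8, did not pass. In the TCA cycle 6 of 32 fell and MDH1, PDK1 and PDK3 rose (6 and 2 adjusted over the list alone, 0.69). In fatty acid uptake and oxidation 13 of 36 fell and FABP4, ACADM, HADHA, HADHB and DECR1 rose (13 and 5 adjusted over the list alone, 0.112). In glycolysis and glucose uptake 9 of 27 fell and SLC2A1, PGAM1 and LDHA rose (9 and 4 adjusted over the list alone, 0.213). In amino acid and ketone catabolism 6 of 25 fell and MCCC2, MUT and HIBCH rose (6 and 3 adjusted over the list alone, 0.405). Examples were the lipase PNPLA2 (-0.81 ± 0.11), the insulin-responsive glucose transporter SLC2A4 (-0.63 ± 0.13), LDHA (0.83 ± 0.11) and the branched-chain transaminase BCAT2 (-1.06 ± 0.11). Mitochondrial dynamics, import and mitophagy genes fell in 14 of 33 cases and rose in 8 (16 and 8 adjusted over the list alone, 0.277), MIEF2 (-1.34 ± 0.12) against SSBP1 (1.06 ± 0.16). In creatine and nucleotide transfer CKM and SLC25A6 fell and CKB, SLC25A5, VDAC2 and AK1 rose among 14 (3 and 5 adjusted over the list alone, 0.822), with the muscle creatine kinase CKM at -1.03 ± 0.12 and the brain form CKB at 1.41 ± 0.21. Without vehicle replicate 3 the call of SLC25A5 was lost (highest adjusted p = 0.0693).

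Several contractile and calcium-handling transcripts fell, and others rose. Of 34 sarcomere and Z-disc genes 13 fell and DES rose (14 and 1 adjusted over the list alone), with MYBPC3 at -0.78 ± 0.10, MYL3 at -0.89 ± 0.13 and MYH7B at -1.22 ± 0.14 beside MYL7. The sarcomere list had a camera adjusted p of 0.0471, and adjusted p = 0.805 with an estimated correlation. The locus annotated as myosin-6, LOC100736765, chosen after its values were seen, fell by 1.88 ± 0.24 (adjusted p = 2.61e-04), from 1240 ± 357 to 337 ± 54.6 CPM. Ventricular chamber genes fell in 6 of 12 cases (6 adjusted over the list alone), among them the ventricular light chain MYL2 (-0.83 ± 0.16) and the potassium channel subunit KCNIP2 (-1.27 ± 0.14). The ventricular list had a camera adjusted p of 0.0471, and adjusted p = 0.597 with an estimated correlation. Calcium handling and ion channel genes fell in 13 of 39 cases and rose in 8 (15 and 10 adjusted over the list alone, camera adjusted p = 0.467). The calcium release channel RYR2 fell by 1.35 ± 0.16 and its anchor JPH2 by 1.19 ± 0.11 on the log2 scale, and the gap junction protein GJA1 rose by 0.78 ± 0.09. Atrial chamber genes split, with MYL7 down and PAM, KCNA5 and DKK3 up among 12 (2 and 3 adjusted over the list alone, 0.773). Conduction system genes split as well, with 2 up, GJC1 among them, and TBX3 down among 10 (3 and 3 adjusted over the list alone, 0.588). Of 5 skeletal muscle genes CASQ1 rose and CKM fell (2 and 1 adjusted over the list alone, 0.755). The calls of KCNA5, DKK3 and TBX3 were each lost when at least 1 vehicle or doxorubicin library was left out (highest adjusted p = 0.0609, 0.131 and 0.194).

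Markers of other cell types also moved with doxorubicin. Endothelial genes fell in 10 of 25 cases and PLVAP rose (12 and 2 adjusted over the list alone), EGFL7 by 1.48 ± 0.13 downward and the water channel AQP1 at -1.11 ± 0.14. The endothelial list had a camera adjusted p of 0.0368, and adjusted p = 0.873 with an estimated correlation. Adipocyte genes fell in 5 of 12 cases, CIDEA, CIDEC, LIPE, GPD1 and the lipid droplet protein PLIN4 (-1.30 ± 0.10), and FABP4 rose (9 and 1 adjusted over the list alone). Without doxorubicin replicate 2 CIDEC had 6 counts left, against 131 with vehicle. The adipocyte list had a camera adjusted p of 0.0498, and adjusted p = 0.61 with an estimated correlation. Ribosomal protein genes fell in 13 of 40 cases and RPS13 rose (13 and 1 adjusted over the list alone), with RPS3 at -0.87 ± 0.11 and RPS19 at -0.98 ± 0.14. The ribosomal list had a camera adjusted p of 0.00368, and adjusted p = 0.873 with an estimated correlation. Fibroblast genes fell in 9 of 18 cases with none rising (9 and 1 adjusted over the list alone, 0.0547), with the actin-severing protein GSN at -1.92 ± 0.27 and PDGFRA at -1.85 ± 0.38 (-2.62 without doxorubicin replicate 1). Of 8 lymphatic endothelial genes 5 fell and 2 rose (5 and 2 adjusted over the list alone, 0.129), LYVE1 (-3.03 ± 0.42), CCL21 (-2.29 ± 0.32), MMRN1, TBX1 and FLT4 against PDPN and PROX1. Schwann cell genes fell in 3 of 11 cases (3 adjusted over the list alone, 0.317), SOX10 and CDH19 among them. Of 19 pericyte and smooth muscle genes PDGFRB, NOTCH3, MYH11, LMOD1 and SMTN fell and DES, MYLK, CASQ2 and PLN rose (5 and 4 adjusted over the list alone, 0.961). Lymphocyte genes rose in 2 of 19 cases (1 adjusted over the list alone, 0.366), PTPRC and JCHAIN. None of 6 neutrophil and mast cell genes passed (0 adjusted over the list alone, 0.562). The calls of ND6, CDH19 and JCHAIN were each lost without doxorubicin replicate 3 (highest adjusted p over all libraries left out = 0.109, 0.06 and 0.234).

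The remaining lists were not called by camera with doxorubicin. Fibrosis and extracellular matrix genes rose in 19 of 44 cases and fell in 7 (20 and 9 adjusted over the list alone, camera adjusted p = 0.059), with the matricellular protein POSTN at 3.02 ± 0.25 and LTBP2 at 2.71 ± 0.29 against the collagenase MMP14 at -1.32 ± 0.15. Inflammatory genes rose in 10 of 31 cases and CCL21, NFKBIA, RELA and LCN2 fell (10 and 4 adjusted over the list alone, 0.177), with the interferon-induced chemokine CXCL10 at 3.01 ± 0.26. Heat shock genes rose in 13 of 32 cases and FBXO32 and TFEB fell (14 and 2 adjusted over the list alone, 0.0547), with HSPH1 at 0.92 ± 0.11 and TFEB at -1.03 ± 0.16. Genes of the integrated stress response and unfolded protein response rose in 11 of 33 cases and ATF5, DDIT4, PPP1R15A and NUPR1 fell (14 and 4 adjusted over the list alone, 0.0547), with the endoplasmic reticulum chaperone HSPA5 at 0.81 ± 0.11. Antioxidant genes rose in 11 of 40 cases and fell in 9 (12 and 9 adjusted over the list alone, 0.69), with the glutathione synthesis gene GCLM at 1.48 ± 0.15. Estrogen receptor genes rose in 6 of 17 cases and CTSD and IGFBP4 fell (6 and 2 adjusted over the list alone, 0.213), with AHR at 0.84 ± 0.14. Genes of doxorubicin transport, metabolism and targets rose in 7 of 24 cases and RARG, AKR7A2, NOS3, ABCC1 and CYP1A1 fell (9 and 6 adjusted over the list alone, 0.773), with the drug efflux pump ABCB1 at 0.84 ± 0.13 and the retinoic acid receptor RARG at -1.24 ± 0.18. Without vehicle replicate 3 the call of NOS3 was lost (adjusted p = 0.073). Circadian clock genes fell in 6 of 19 cases and BHLHE40, RORA and NFIL3 rose (6 and 3 adjusted over the list alone, 0.562), with the output factors DBP (-1.37 ± 0.25) and TEF (-0.84 ± 0.13). Immediate early genes fell in 7 of 25 cases and rose in 6 (7 and 8 adjusted over the list alone, 0.983). Lists with under 5 tested members had no list test: among erythroid genes GYPC fell, among sex-linked genes DDX3X rose, and no mesothelial gene passed.

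With doxorubicin camera called 11 of 43 lists, 6 upward and 5 downward, and none had an adjusted p below 0.326 with an estimated correlation. Without formononetin replicate 2, 7 of these calls stayed, 1 of them downward. Without formononetin replicate 1, or with a replicate block, 8 stayed, 2 of them downward. The calls of the sarcomere, ventricular, endothelial and adipocyte lists were lost when any of several libraries was left out (vehicle replicate 1 for the first 3, vehicle replicate 2 or 3 for adipocytes, doxorubicin replicate 1 for all 4), and the ribosomal (0.116) and endothelial (0.0831) calls were lost with fry. Fry called 15 lists, 9 of them also called by camera. The other 6 were the integrated stress response (0.00861), inflammatory (0.0192), estrogen receptor (0.0192), heat shock (0.024) and conduction system (0.0235) lists, upward, and the lymphatic endothelial list (0.0192), downward. Relabelled splits of the same 6 libraries, which keep part of the group difference, called up to 20 lists and 0 genes.

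**Figure D1:**
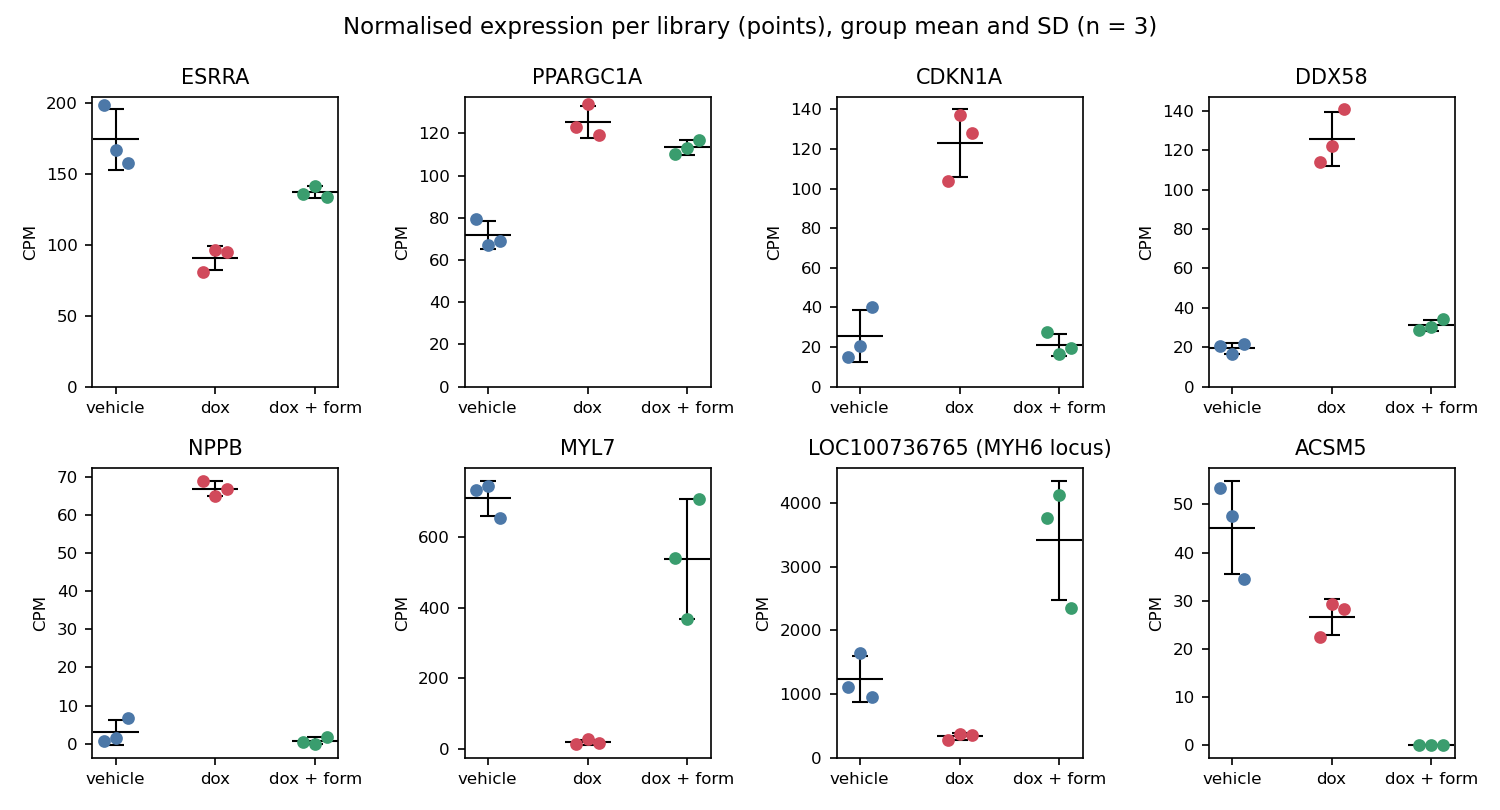
Normalised expression (CPM, linear axes) of 8 genes in the 9 libraries, as points, with the group mean (bar) and SD (whiskers, n = 3). ESRRA, MYL7 and the myosin-6 locus were lower with doxorubicin than in both other groups, CDKN1A, DDX58 and NPPB were higher, PPARGC1A was higher than vehicle in both treated groups, and ACSM5 was at 0 in all 3 libraries with formononetin.

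With formononetin added to doxorubicin many of these genes stood nearer to vehicle levels. No group received formononetin alone, so its own effect cannot be told apart from an effect on the response to doxorubicin. NPPB went from 66.8 ± 1.97 CPM with doxorubicin to 0.751 ± 0.87 CPM with formononetin added, CDKN1A from 123 ± 17.2 to 21.1 ± 5.60 CPM, and MYL7 from 18.5 ± 7.23 to 539 ± 170 CPM (n = 3 each). ESRRA went from 90.9 ± 8.35 to 137 ± 4.13 CPM. Of 14846 genes 4173 changed between doxorubicin plus formononetin and doxorubicin, 2176 upward and 1997 downward, or 1548 upward and 2709 downward with library totals as the only scaling. The groups did not overlap for 42.2% of genes, where chance gives 10%.

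The 8 largest rises with formononetin added were in LIPM, a lipase, SLA-5 (5.05 ± 0.76), a class I antigen whose reads can be shared with other SLA genes, MYL7 (4.86 ± 0.30), HMCN2 (4.48 ± 0.51), EMILIN3 (4.45 ± 0.48), AGT (4.20 ± 0.59), the neurotrophin receptor NTRK2 (4.18 ± 0.78) and MYOC (4.14 ± 0.74). LIPM had 1 count over the doxorubicin libraries and 342 with formononetin added, a ratio of 357 with a 95% interval from 63.6 to 14100. ACSM5, a mitochondrial medium-chain acyl-CoA synthetase, had 0 counts in all 3 libraries with formononetin and 1361 over the doxorubicin libraries, so it was at least 145-fold lower, against a floor of 3 counts per library (0.184 CPM). The other large falls were in NPPB (-6.52 ± 0.76), CHI3L1 (-4.85 ± 0.86), MYL1 (-4.32 ± 0.78), the metalloprotease TLL2 (-4.18 ± 0.78), the phosphatase DUSP13 (-4.13 ± 0.68), the collagen-triple-helix protein CTHRC1 (-4.07 ± 0.70) and RAB3B (-4.00 ± 0.39). The adjusted p-values of these 16 genes lay between 7.40e-06 (ACSM5) and 0.00305 (TLL2) by the edgeR quasi-likelihood test. Without doxorubicin replicate 1, HMCN2 was at 6.14, EMILIN3 at 5.11, AGT at 5.45 and NTRK2 at 5.53. Without doxorubicin replicate 3, LIPM had 0 counts left in the doxorubicin group, which made the rise at least 41.3-fold, and CHI3L1 was at -3.48. Among the formononetin libraries, leaving out replicate 1 put MYL1 at -6.44 and CTHRC1 at -4.81, and left TLL2 with 6 counts against 293 with doxorubicin. Leaving out replicate 2 put NTRK2 at 3.44, NPPB at -5.90, TLL2 at -3.57, DUSP13 at -3.52 and CTHRC1 at -3.46. Leaving out replicate 3 put SLA-5 at 4.29, NPPB at -7.93 and DUSP13 at -5.22. By limma-voom the calls of SLA-5 (adjusted p = 0.0661), MYOC (0.0614) and CHI3L1 (0.173) were lost.

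Many members of the interferon, damage and stress lists fell when formononetin was added. Interferon response genes fell in 32 of 43 cases and SLA-3 rose (35 and 1 adjusted over the list alone), with DDX58 at -2.01 ± 0.13 and the RNA sensor IFIH1 at -1.58 ± 0.16. SLA-2, at -2.17 ± 0.15, had already fallen with doxorubicin and so moved further from vehicle. Reads of SLA-2 and SLA-3 can be shared with other SLA genes. The interferon list had a camera adjusted p of 8.38e-13, and adjusted p = 0.626 with an estimated correlation. Among p53 targets 15 of 40 fell and GADD45G, POLH and FDXR rose (16 and 3 adjusted over the list alone), with CDKN1A at -2.54 ± 0.31, ZMAT3 at -1.93 ± 0.16, BTG2 at -1.79 ± 0.14 and MDM2 at -1.18 ± 0.10. The p53 list had a camera adjusted p of 0.00586, and adjusted p = 0.626 with an estimated correlation. Death genes fell in 11 of 30 cases and BCL2L1 and BAK1 rose (11 and 2 adjusted over the list alone), with CASP1 at -2.34 ± 0.24, DFNA5 at -1.16 ± 0.10 and the survival factor MCL1 at -0.97 ± 0.12. The death gene list had a camera adjusted p of 0.00586, and adjusted p = 0.626 with an estimated correlation. Genes of the integrated stress response and unfolded protein response fell in 15 of 33 cases and DDIT4, NUPR1 and PSAT1 rose (15 and 4 adjusted over the list alone), with HSPA5 at -1.24 ± 0.11 and DNAJB9 at -1.44 ± 0.21. The stress response list had a camera adjusted p of 0.00586, and adjusted p = 0.626 with an estimated correlation. Heat shock genes fell in 14 of 32 cases and rose in 2, TFEB among them (14 and 3 adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.826 with an estimated correlation). Cardiac stress and fetal genes fell in 12 of 30 cases and MYC, ACTA1 and SPP1 rose (12 and 3 adjusted over the list alone), with CTGF at -2.18 ± 0.15, RCAN1 at -1.67 ± 0.16 and XIRP2 at -1.53 ± 0.23. The cardiac stress list had a camera adjusted p of 0.0348, and adjusted p = 0.626 with an estimated correlation. Cell cycle genes fell in 10 of 42 cases (9 adjusted over the list alone), with TYMS at -1.94 ± 0.36 (camera adjusted p = 3.02e-04, and adjusted p = 0.681 with an estimated correlation). Macrophage genes fell in 11 of 23 cases (11 adjusted over the list alone), with AIF1 at -1.61 ± 0.23 and the scavenger receptor MSR1 at -2.00 ± 0.31. The macrophage list had a camera adjusted p of 0.00279, and adjusted p = 0.681 with an estimated correlation. By its median log2 deviation from the rest of its group, the second formononetin library lay below all other libraries in some of these lists. These were heat shock (-0.2, against -0.12 or higher), death (-0.18, -0.09), stress response (-0.11, -0.07) and cardiac stress genes (-0.14, -0.08). For the interferon, p53, cell cycle and macrophage lists it lay within their range.

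ESRRA and some ERR-alpha target genes rose when formononetin was added. ESRRA rose by 0.59 ± 0.11 (adjusted p = 0.00354), RXRA by 1.26 ± 0.13 (1.46e-04) and PERM1 by 0.90 ± 0.14 (0.00123), while PPARGC1A (-0.15 ± 0.10, adjusted p = 0.304) and ESRRG (-0.04 ± 0.13, adjusted p = 0.832) did not pass. Of 23 regulators 4 rose, SIRT3 included, and PRKAA1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.747). Of 39 ERR-alpha target genes 13 rose, 2 fell and 24 did not pass (15 and 2 adjusted over the list alone). ESRRA and PERM1 belong to both lists and are among the 13. OGDH rose by 0.69 ± 0.10, IDH3G by 0.77 ± 0.12 and CPT1B by 0.62 ± 0.11. PDK4, the kinase that shuts off pyruvate dehydrogenase, fell by 1.82 ± 0.26 and ACADM also fell. The target gene list had a camera adjusted p of 0.00703, and adjusted p = 0.826 with an estimated correlation. Complex I subunits rose in 13 of 37 cases and NDUFS5 and NDUFB1 fell (13 and 2 adjusted over the list alone), with NDUFA3 at 1.88 ± 0.15 and NDUFS7 at 0.67 ± 0.13. The complex I list had a camera adjusted p of 0.0275, and adjusted p = 0.87 with an estimated correlation. Mitochondrially encoded subunits rose in 6 of 13 cases (6 adjusted over the list alone), with COX3 at 0.87 ± 0.12 and CYTB at 0.60 ± 0.11. ATP8, which can share reads with ATP6, was at 3.17 ± 0.33. The mitochondrially encoded list had a camera adjusted p of 0.015, and adjusted p = 0.826 with an estimated correlation. In the TCA cycle 8 of 32 rose and PDK4 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.826 with an estimated correlation). In the second formononetin library the median log2 deviation from the other 2 libraries of its group lay below that of the other 8 libraries for ERR-alpha target genes (-0.3, against -0.22 or higher), complex I subunits (-0.41, -0.26), mitochondrially encoded subunits (-0.43, -0.09) and TCA cycle and pyruvate dehydrogenase (-0.28, -0.21). Without it these 4 lists were called at an adjusted p of 1.80e-04 for each of the first 3 and 0.00271 for the last. In amino acid and ketone catabolism 7 of 25 rose (7 adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.826 with an estimated correlation), with HSD17B10 at 1.70 ± 0.15 and BCAT2 at 0.81 ± 0.11.

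Other energy lists were not called by camera or fry with formononetin added. Without the second formononetin library camera also called ATP synthase subunits (0.0198), fatty acid uptake and oxidation (0.0459) and mitochondrial dynamics, import and mitophagy (0.042). Fatty acid uptake and oxidation genes rose in 9 of 36 cases and CPT1A, PLIN2 and ACADM fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.181), with PNPLA2 at 0.90 ± 0.11 and the fatty acid transporter SLC27A6 at 2.21 ± 0.45. Glycolysis genes rose in 11 of 27 cases and LDHA (-1.08 ± 0.11) and PGAM1 fell (11 and 2 adjusted over the list alone, 0.062). Mitochondrial dynamics genes rose in 14 of 33 cases and fell in 6 (14 and 7 adjusted over the list alone, 0.0841). ATP synthase subunits rose in 5 of 17 cases (5 adjusted over the list alone, 0.216), ATP5D, ATP5G2, ATP5G3, ATP5I and ATP5J2. In complexes II and III UQCRB rose (1.26 ± 0.14, 1 of 7 adjusted over the list alone, 0.53). Among complex III subunits matched only by description, and chosen after their values were seen, LOC100156879 (0.42 ± 0.14), LOC100524873 (0.50 ± 0.14) and LOC100525869 (0.52 ± 0.13) also rose. In complex IV COX8H (1.26 ± 0.21) rose and COX7A2 fell (1 and 1 adjusted over the list alone, 0.494). In creatine and nucleotide transfer SLC25A6 (1.32 ± 0.10) and CKM (1.14 ± 0.12) rose and CKB fell (2 and 1 adjusted over the list alone, 0.568). The calls of COX7A2 and CKB were lost when single libraries were left out, doxorubicin replicates 1 and 2 among them (highest adjusted p = 0.145 and 0.14).

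Among contractile and cell type lists, Schwann cell and neuronal genes rose in 7 of 11 cases and UCHL1 fell (8 and 1 adjusted over the list alone), with the glial transcription factor SOX10 at 2.77 ± 0.44 and CDH19 at 1.62 ± 0.31. The Schwann cell list had a camera adjusted p of 0.0106, and adjusted p = 0.652 with an estimated correlation. Fibroblast genes rose in 8 of 18 cases (9 adjusted over the list alone), with GSN at 1.80 ± 0.27, SCARA5 at 4.04 ± 0.69 (6.52 without doxorubicin replicate 1) and PDGFRL at 1.75 ± 0.33. The fibroblast list had a camera adjusted p of 0.00701, and adjusted p = 0.826 with an estimated correlation. Both lists were raised in the second formononetin library, whose median log2 deviation from the other 2 libraries of its group lay above that of the other 8 libraries (0.56 against at most 0.37 for Schwann cell and neuronal genes, 0.54 against 0.41 for fibroblast genes). Without it their camera adjusted p was 0.0341 and 0.047. Adipocyte genes rose in 4 of 12 cases, PLIN4 (0.76 ± 0.10), GPD1, DGAT2 and FASN (7 adjusted over the list alone, camera adjusted p = 0.0154, and adjusted p = 0.652 with an estimated correlation). Endothelial genes rose in 5 of 25 cases, AQP1 (1.22 ± 0.14), FLT1 (1.06 ± 0.16), EGFL7, VWF and CDH5, with PLVAP falling (5 and 1 adjusted over the list alone, camera adjusted p = 0.0188, and adjusted p = 0.826 with an estimated correlation). Sarcomere genes rose in 10 of 34 cases and DES, NEXN and CSRP3 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.106). The myosin-6 locus LOC100736765, chosen after its values were seen, rose by 3.34 ± 0.25 (adjusted p = 2.75e-05) to 3420 ± 934 CPM. The call of FASN was lost without doxorubicin replicate 1 or 3 or formononetin replicate 1 or 2 (highest adjusted p = 0.107). RYR2 rose by 1.59 ± 0.16 and GJA1 fell by 0.82 ± 0.09 on the log2 scale in the calcium handling list, where 10 of 39 rose and 10 fell (11 and 10 adjusted over the list alone, 0.772).

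Lists without a call by camera in this comparison were the ventricular (KCNIP2 and PRDM16 up of 12, camera adjusted p = 0.181), atrial (MYL7 up, PAM, DKK3 and KCNA5 down of 12, 0.772), conduction (TBX3 and CNTN2 up, 2 down of 10, GJC1 among them, 0.772) and skeletal muscle genes (CKM up, CASQ1 and TNNT1 down of 5, 0.6). The same numbers passed adjusted over the list alone. The lymphatic (6 up, PROX1 and PDPN down of 8, 0.062, with such a deviation of 0.79 in the second formononetin library against at most 0.04 in the others), pericyte and smooth muscle (PDGFRB, NOTCH3, MYH11, LMOD1 and SMTN up, KCNJ8, DES and CASQ2 down of 19, 0.286), lymphocyte (CCL5 up of 19, 0.984) and neutrophil and mast cell lists (0 of 6, 0.772) were not called by camera either. Adjusted over the list alone these counts were the same, apart from 0 for lymphocytes. Fibrosis genes rose in 9 of 44 cases and fell in 13 (11 and 15 adjusted over the list alone, 0.19), with POSTN at -2.90 ± 0.25 and LTBP2 at -2.76 ± 0.30 against the metalloprotease inhibitor TIMP3 at 0.83 ± 0.09. For the fibrosis list such a deviation was 0.57 in the second formononetin library, against at most 0.37 in the others. Inflammatory genes rose in 6 of 31 cases and fell in 8 (6 and 8 adjusted over the list alone, 0.772), with CXCL10 at -2.33 ± 0.25 and the NF-kappa-B inhibitor NFKBIA at 1.48 ± 0.14. Antioxidant genes rose in 6 of 40 cases and fell in 9 (8 and 10 adjusted over the list alone, 0.371). Of 24 doxorubicin transport and target genes RARG, AKR7A2 and ABCC1 rose and TOP2A, TDP2, AKR1A1 and ABCB1 fell (3 and 4 adjusted over the list alone, 0.996). Estrogen receptor genes fell in 3 of 17 cases (3 adjusted over the list alone, 0.883), XBP1, PTGES3 and HSP90AA1. Circadian clock genes rose in 9 of 19 cases and ARNTL, BHLHE40, RORA and NFIL3 fell (9 and 4 adjusted over the list alone, 0.0726), with DBP at 1.72 ± 0.25 and PER3 at 0.97 ± 0.18. Ribosomal protein genes rose in 6 of 40 cases and RPL10A and RPS13 fell (5 and 2 adjusted over the list alone, 0.217). Immediate early genes rose in 7 of 25 cases and fell in 8 (8 and 8 adjusted over the list alone, 0.772). Among lists too small for a list test, GYPC and HBB rose in the erythroid list and KRT8 fell in the mesothelial list. No sex-linked gene passed, but only 3 of 12 listed entries were tested, so the sex of the animals cannot be judged from this. The calls of HSP90AA1, CCL5, HBB, KRT8 and RPS13 were each lost without doxorubicin replicate 3 (highest adjusted p over all libraries left out = 0.0733, 0.141, 0.121, 0.137 and 0.0599). Without formononetin replicate 2 CNTN2 was at 2.16.

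Camera called 17 lists in this comparison, 9 upward and 8 downward, and none had an adjusted p below 0.626 with an estimated correlation. With fry the ERR-alpha target (0.105), complex I (0.259), mitochondrially encoded (0.0704), TCA cycle (0.117), amino acid (0.106), endothelial (0.105) and fibroblast (0.117) calls were lost. Fry called 13 lists, 10 of them also called by camera, and the other 3 were the circadian clock (0.0127, upward), conduction system (0.0262, downward) and lymphatic endothelial (0.0263, upward) lists. Leaving out the third doxorubicin plus formononetin library ended the calls of the ERR-alpha target genes (0.0761), mitochondrially encoded subunits (0.135), complex I subunits (0.142), TCA cycle and pyruvate dehydrogenase (0.244), amino acid and ketone catabolism (0.135), endothelial genes (0.0761), heat shock and proteostasis (0.0757) and cardiac stress and fetal genes (0.0997). Leaving out the second ended that of heat shock and proteostasis (0.0634). Of the 17 calls 12 stayed without doxorubicin replicate 2, and 13 without doxorubicin replicate 1 or without formononetin replicate 1. A relabelled split of the same 6 libraries, which keeps part of the group difference, also called 17 lists and 0 genes.

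Of the 2421 genes that rose with doxorubicin, 1450 (59.9%) fell when formononetin was added, and of the 2526 that fell, 1651 (65.4%) rose, which makes 3101 reversed genes. In the same direction in both steps 9 genes rose and 8 fell. Against vehicle, the median log2 fold change of the genes that rose with doxorubicin was 0.68 without and 0.16 with formononetin, and that of the genes that fell was -0.77 without and -0.16 with it. Formononetin libraries were nearer to vehicle for 95.4% of the genes that rose and 96.8% of those that fell. The doxorubicin libraries enter both comparisons. In 20 simulated datasets in which formononetin changed nothing, 0.05 genes were reversed on average and 59.8% of doxorubicin genes lay nearer to vehicle, against 3101 and 96.1% observed. The covariance of the log2 fold changes of both steps was -0.561, against -0.0725 in those simulations, and their correlation was -0.719, against -0.205. In simulations in which no group differed, the covariance was -0.0702 and the correlation -0.499. Independent lists of these sizes would share 325.7 genes that rose and then fell, and 370.2 that fell and then rose. With 3 libraries the doxorubicin group cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. The simulations drew each library independently around its group mean, so they hold no shift that sets the doxorubicin libraries apart from the formononetin libraries. Splits that kept the 3 doxorubicin libraries together and mixed the others gave 2770, 2698 and 2695 reversed genes. The excess over the simulations thus mostly shows that the doxorubicin libraries stood apart, and cannot tell formononetin from another difference between the groups.

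**Figure D2:**
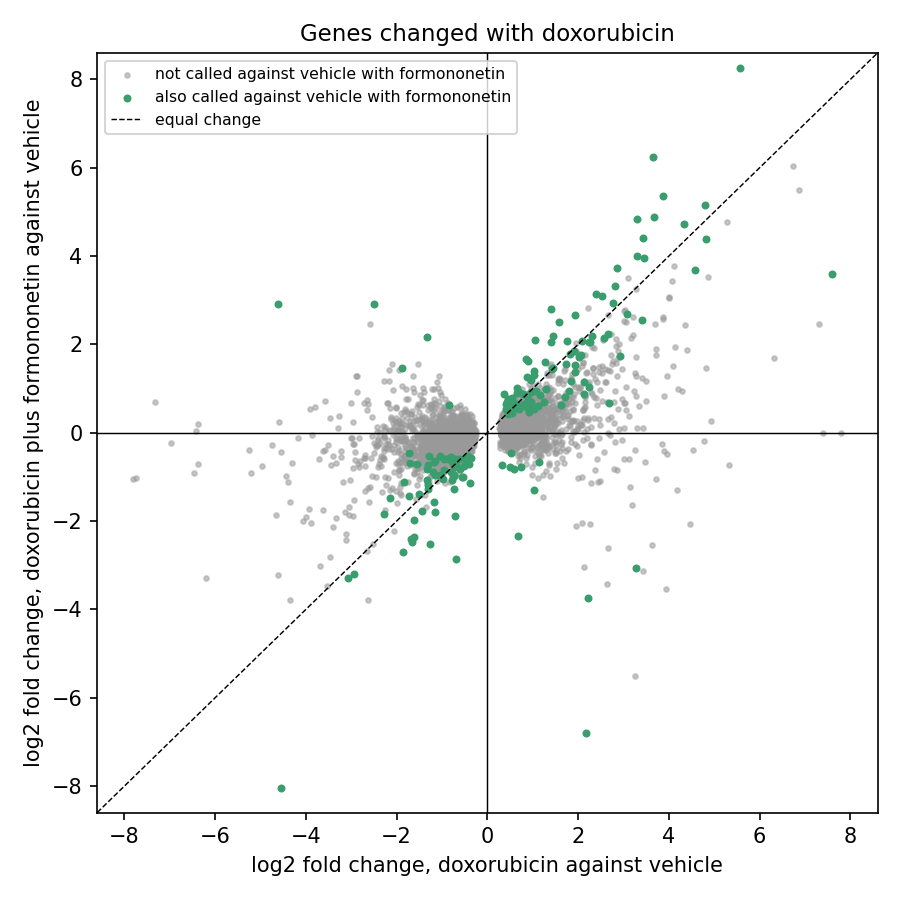
Log2 fold change against vehicle with doxorubicin (horizontal) and with doxorubicin plus formononetin (vertical) for the 4947 genes called with doxorubicin, of which 7 lie outside the axes; the dashed line marks equal change, and green points are genes also called against vehicle with formononetin. Most points lie nearer to the horizontal line at 0 than to the dashed line, with medians of 0.16 and -0.16 for the genes that rose and fell with doxorubicin.

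Doxorubicin plus formononetin was also set against vehicle, which asks what still differed with both compounds. Only 262 of 14846 genes changed by the edgeR quasi-likelihood test, 142 upward and 120 downward (104 and 196 with library totals as the only scaling), and the groups did not overlap for 23.6% of genes, where chance gives 10%. ACSM5 was at 0 counts with formononetin and at 45.2 ± 9.68 CPM with vehicle, at least 246-fold lower against a floor of 3 counts per library (0.184 CPM). ESRRA stood at 137 ± 4.13 CPM against 175 ± 21.6 CPM with vehicle (n = 3 each) and did not pass (-0.35 ± 0.11, adjusted p = 0.156). PPARGC1B remained low at 33.4 ± 5.92 CPM against 81.1 ± 9.75 CPM, and PPARGC1A remained high at 114 ± 3.13 CPM against 71.8 ± 6.62 CPM.

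Among the largest rises against vehicle were those of the photopigment gene OPN4 (4.41 ± 0.68), the calcium channel subunit CACNA2D3 (3.73 ± 0.49), the neurotrophin receptor NGFR (3.63 ± 0.76), BEND6 (3.15 ± 0.28), the cytokine receptor subunit IL20RA (3.11 ± 0.40) and the adrenergic receptor ADRA1B (2.81 ± 0.36). After ACSM5, the largest falls were in SLA-2 (-2.85 ± 0.16), which can share reads with other SLA genes, the fucose mutarotase FUOM (-2.71 ± 0.28), ADGRF2 (-2.58 ± 0.22), the riboflavin transporter SLC52A3 (-2.48 ± 0.40), the metallothionein MT3 (-2.40 ± 0.34), the extracellular chaperone CLU (-2.36 ± 0.15) and PDK4 (-2.03 ± 0.26). Their adjusted p-values lay between 4.69e-06 (SLA-2 and ACSM5) and 0.0372 (NGFR). The call of NGFR was lost when any vehicle library, or the first or second formononetin library, was left out (highest adjusted p = 0.295), and without the second formononetin library NGFR was at 2.50. Without vehicle replicate 3 the calls of OPN4 and SLC52A3 were lost (highest adjusted p = 0.257 and 0.0596). By limma-voom those of OPN4 and IL20RA (0.0547) were lost.

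Few list members passed against vehicle. Among regulators of mitochondrial genes PPARGC1A rose (0.66 ± 0.10, adjusted p = 0.00899) and PPARGC1B fell (-1.28 ± 0.15, adjusted p = 0.00162). The first of these calls was lost without vehicle replicate 2 or 3 (highest adjusted p = 0.0645). ERR-alpha target genes LDHD (1.36 ± 0.25), HADHA (0.57 ± 0.11) and HADHB (0.69 ± 0.14) rose and PDK4 fell among 39. These 3 rises were lost without any 1 vehicle library (highest adjusted p = 0.131, 0.148 and 0.177). FKBP5, a chaperone of steroid receptors, rose by 0.91 ± 0.12 (adjusted p = 0.00364), the malonyl-CoA decarboxylase MLYCD fell by 1.57 ± 0.20 and CAMK2B by 0.99 ± 0.10 on the log2 scale, and the nuclear receptor NR4A3 rose by 2.41 ± 0.36. The myosin-6 locus LOC100736765, chosen after its values were seen, rose by 1.46 ± 0.24 (adjusted p = 0.0108). NPPB (0.751 ± 0.87 against 2.99 ± 3.28 CPM, adjusted p = 0.258), CDKN1A (21.1 ± 5.60 against 25.4 ± 13.2 CPM, 0.698), NPPA (8.30 ± 12.1 against 99.0 ± 99.6 CPM, 0.163), ESRRG (47.5 ± 4.31 against 36.4 ± 5.02 CPM, 0.181) and TOP2B (132 ± 18.7 against 144 ± 4.34 CPM, 0.621) did not pass.

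Camera called 6 lists against vehicle. Mitochondrially encoded subunits had a median log2 fold change of 0.38, and ND1 (0.64 ± 0.13) and ND2 (0.66 ± 0.14) rose among 13 (10 adjusted over the list alone, camera adjusted p = 3.31e-06, and adjusted p = 0.959 with an estimated correlation). Interferon response genes rose in 6 of 43 cases and SLA-2 fell (15 and 1 adjusted over the list alone), with a median of 0.44, DDX58 at 0.67 ± 0.13 and SLA-3 at 1.68 ± 0.22. The interferon list had a camera adjusted p of 5.91e-08, and adjusted p = 0.959 with an estimated correlation. Schwann cell and neuronal genes rose in 3 of 11 cases, S100B among them (4 adjusted over the list alone, camera adjusted p = 0.023, and adjusted p = 0.959 with an estimated correlation). In the TCA cycle list PDK1 (0.88 ± 0.13) rose and PDK4 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.0235, and adjusted p = 0.959 with an estimated correlation). No cell cycle gene passed (0 adjusted over the list alone, upward, camera adjusted p = 0.0245, and adjusted p = 0.959 with an estimated correlation), nor did any ribosomal protein gene (2 lower adjusted over the list alone, downward, camera adjusted p = 4.58e-04, and adjusted p = 0.959 with an estimated correlation). All 6 calls were lost with fry (adjusted p from 0.242 to 0.594). Relabelled splits of the 6 libraries, which keep part of the group difference, called up to 17 lists. The calls of ND1, ND2, DDX58, S100B and PDK1 were each lost without vehicle replicate 3 (highest adjusted p = 0.166, 0.17, 0.121, 0.205 and 0.05). Without the second formononetin library the call of Schwann cell and neuronal genes was lost (0.0879), and camera also called ERR-alpha target genes (0.0186), complex I subunits (0.0331), ATP synthase subunits (0.0331) and mitochondrial creatine and nucleotide transfer (0.0458). Without the first formononetin library 3 of the 6 list calls stayed. The count of 262 genes rested on few libraries: it was 103, 94 and 64 without vehicle replicates 1, 2 and 3, 155 without doxorubicin replicate 2, and 120 and 465 without doxorubicin plus formononetin replicates 1 and 3.

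Of the 262 genes, 161 had changed in the same direction with doxorubicin, 94 upward and 67 downward, 16 had changed in the opposite direction and 85 had not been called with doxorubicin. Independent lists of these sizes would share 23.2 genes upward and 20.4 downward, and in simulated data in which nothing changes the shared vehicle libraries gave 0.05 genes called the same way in both. Where formononetin changes nothing the simulation gave 4280. Both comparisons use the same vehicle libraries, which cannot be split into parts of at least 2, so part of this overlap may come from them. The covariance of both sets of log2 fold changes was 0.205, against 0.0694 where nothing changes, and their correlation was 0.354, against 0.495.

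**Figure D3:**
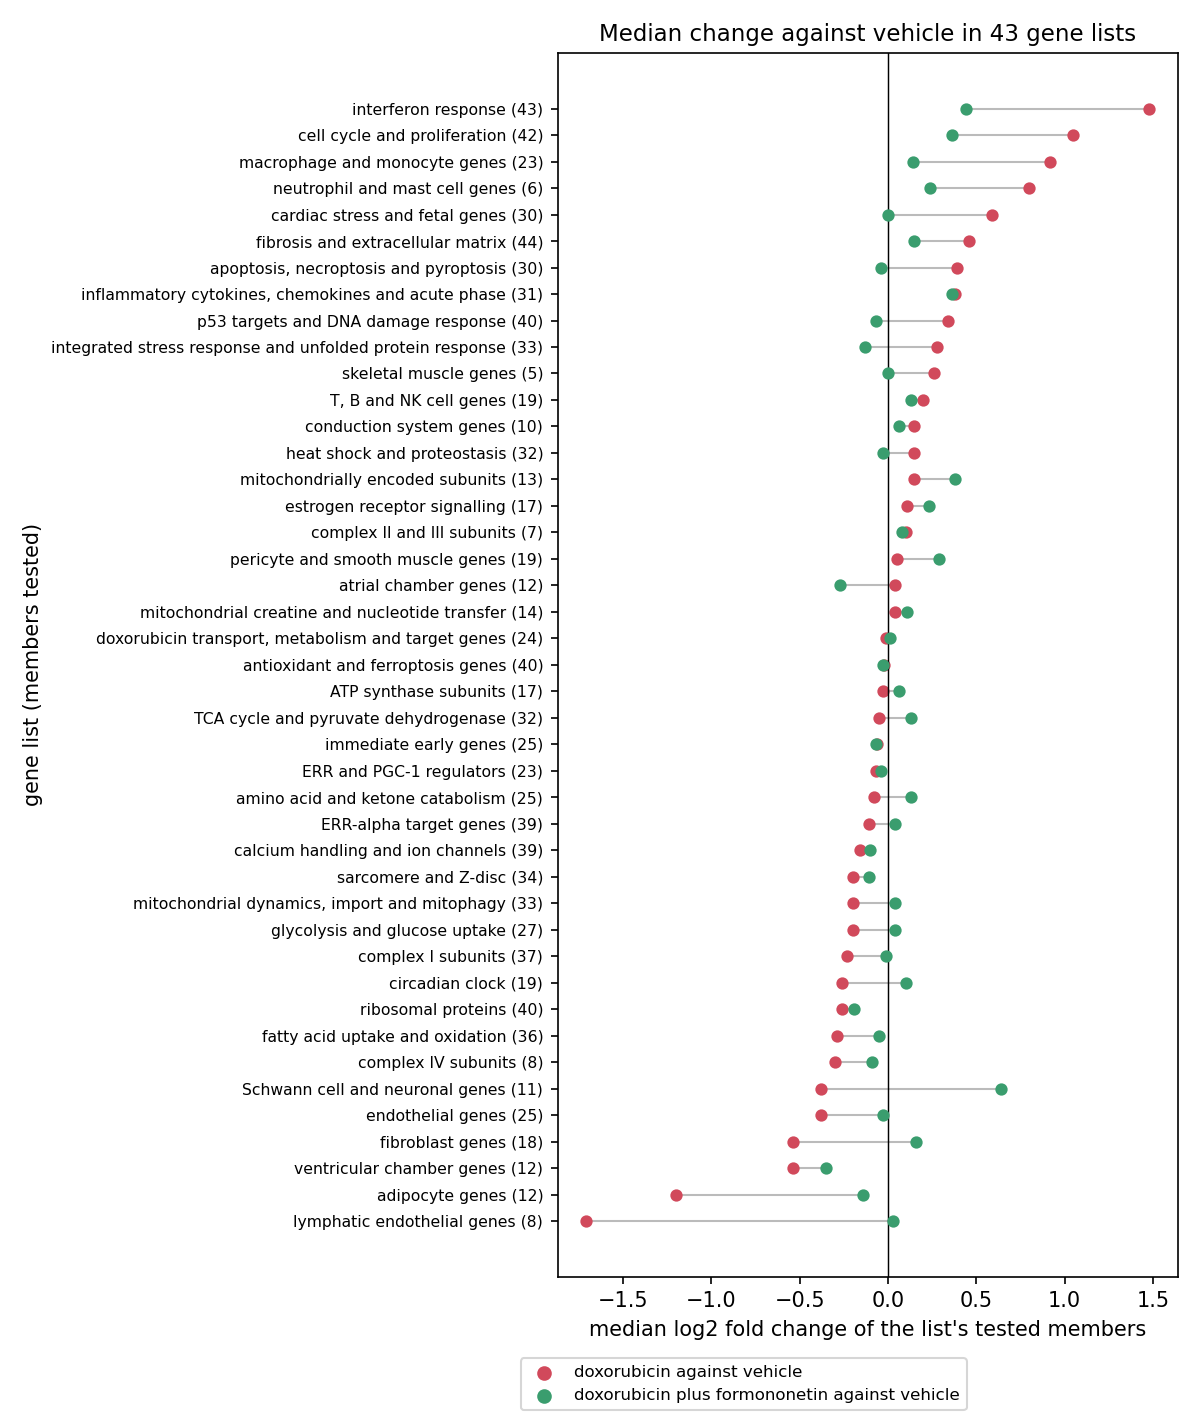
Median log2 fold change against vehicle of the tested members of 43 gene lists (member number in brackets), with doxorubicin in red and with doxorubicin plus formononetin in green, joined by a grey line. The interferon list had medians of 1.48 and 0.44, and the lymphatic endothelial list the lowest median with doxorubicin, -1.71.

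Positions are given for the genes most referred to, as chromosome, start and end on the pig assembly Sscrofa11.1 in the RefSeq annotation. ESRRA (gene ID 100322868) lies on chromosome 2 from 7803504 to 7812868, PPARGC1A (397013) on chromosome 8 from 17841844 to 18527953, NPPB (396844) on chromosome 6 from 71930374 to 71931843 and CDKN1A (100152215) on chromosome 7 from 32354776 to 32363771. MYL7 (100514437) lies on chromosome 18 from 51026436 to 51028917, DDX58 (396723) on chromosome 10 from 33891720 to 33976151 and ACSM5 (100511318) on chromosome 3 from 25393121 to 25422551. Counts cover whole genes, so no part of a gene can be singled out.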

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

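No called gene or list reversed its direction under the alternatives it was followed through, but counts moved, and so did the balance of higher and lower genes. With library totals as the only scaling the side with more genes changed in each comparison: 2520 higher and 2192 lower with doxorubicin (2421 and 2526 in the report), 1548 and 2709 with formononetin added (2176 and 1997), and 104 and 196 for doxorubicin plus formononetin against vehicle (142 and 120). It also changed with limma-voom, to 2001 and 2156 with formononetin added and 81 and 109 against vehicle. Other alternatives also put nearly even balances on the other side, such as DESeq2 with 2718 and 2692 for doxorubicin, so which side holds more genes depends on the processing. Most genes named only to complete a count were not followed, and lists were not run with upper quartile scaling, library totals only, DESeq2, limma-voom, only the 6 libraries compared, glmTreat or other thresholds. Gene length correction, list members matched by description and the estimated correlation over 8 libraries were chosen after seeing the data. Genes changed with doxorubicin against vehicle numbered 2773 at an adjusted p of 0.01 and 927 when tested against a 1.5-fold change with glmTreat, against 4947 in the report, and those changed by adding formononetin 1982 and 680, against 4173. Genes differing among the 3 groups numbered 2609 and reversed genes 1473 at an adjusted p of 0.01, against 5122 and 3101. Doxorubicin plus formononetin against vehicle was the least stable, with 262 genes in the report, 748 with DESeq2, 488 without a filter, 118 with only the 6 libraries compared, 560 at an adjusted p of 0.1, 69 at 0.01, 64 with glmTreat and 64 to 465 with 1 library left out. Stricter thresholds give fewer genes by construction. For the other shifts the cause was not tested.

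With a replicate block this comparison held 124 genes, doxorubicin against vehicle 4327, adding formononetin 3486, and 2605 genes were reversed. The replicates share only a number, and no pairing is stated. Correlations between libraries of the same number lay from -0.20 to 0.03, and 0 of 9 correlated best with their own number.

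Gene lists called with doxorubicin numbered 19 without a filter, 15 with fry and 7 to 14 with 1 library left out, against 11 in the report. With formononetin added they numbered 9 to 21, against 17, and against vehicle 3 to 9, or 0 with fry, against 6. With an estimated correlation 0 lists were called in each of the 3 comparisons, and 0 over 8 libraries. An estimated correlation from 9 or 8 libraries is itself imprecise, and the cause of the lost calls was not tested. With 1 library left out, 3316 to 6657 genes changed with doxorubicin, 2801 to 4436 with formononetin added, and 2125 to 3412 were reversed. An arm left with 2 libraries was assumed to vary like the others. Among values of named genes under the alternatives 6761 kept a call, 278 lost it, 168 gained one, 29 uncalled values changed sign and 0 reversed. Genes at few counts are limited by depth.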

Other observations

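The tests on atrial tissue and on ACSM reads, and the list count of the library that stood apart, were chosen only after the result was seen. The natriuretic peptide genes parted: NPPB was near 66.8 CPM in all doxorubicin libraries, while NPPA was at 40.2, 214 and 42.7 CPM with vehicle, 36.1, 3.49 and 2.46 CPM with doxorubicin and 0.973, 1.72 and 22.2 CPM with formononetin added. Of 4173 genes that changed when formononetin was added to doxorubicin, 1055 had not been called with doxorubicin, 516 higher and 539 lower.

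MYL7 was nearly lost with doxorubicin and rose by 4.86 on the log2 scale with formononetin added. The myosin-6 locus LOC100736765, an atrial myosin heavy chain outside the atrial list, moved with it (-1.88 with doxorubicin and 3.34 with formononetin added), as less atrial tissue in the doxorubicin samples would have it. Atrial content may well differ among samples, since MYL4 was at 6.55, 39.6 and 7.81 CPM with vehicle, 10.7, 1.3 and 0.307 CPM with doxorubicin and 0.548, 1.49 and 6.29 CPM with formononetin added, and NPPA and SLN were also highest of their group in the second vehicle and first doxorubicin libraries. MYL7 did not follow it, at 744 and 13.7 CPM in those libraries, and the highest change among the other atrial list members with formononetin added was 0.41. Less atrial tissue is thus argued against as the whole cause of the MYL7 change, and what moved both myosin genes was not tested.

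ERR-alpha target genes were reversed in 13 of 18 cases (72.2%), ESRRA and PERM1 among them. Of other genes changed with doxorubicin 62.6% were reversed (Fisher exact p = 0.472). Across the lists given the same test the share ran from 33.3% (ventricular chamber and adipocyte genes) to 100% (circadian clock and lymphatic endothelial genes). None passed after adjustment over these lists (lowest Fisher exact adjusted p = 0.296). Whether the receptor's targets come back more often than other genes stays open with so few members, so the values could hold either way.

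ACSM5 was at 0 counts in all libraries with formononetin. Reads assigned to another ACSM gene are argued against, since the summed counts of the other ACSM genes changed by -29 where 1361 ACSM5 counts were lost. Of genes at 2 CPM or more in at least 3 libraries and at 0 in all others, also at least 3, 5 followed the groups, ACSM5 among them, and 0 crossed them. Genes that differed in fewer libraries were not counted. Treatment cannot be told apart from a genotype shared by the animals of a group, such as littermates, because each group has its own libraries. Nor can it be told apart from the libraries of a group coming from a single animal. The same holds for every gene called in these comparisons.

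The second doxorubicin plus formononetin library stood apart. Of its genes at 100 CPM or more, 0.83% differed over 2-fold from the other 2 libraries, the same as the highest share among the 6 libraries of the other groups, while below 100 CPM it was 20%, against at most 5.99% in those. The other 2 libraries of its own group have it in their reference and are no benchmark. Lower molecular complexity may be part of the cause, and 0.83% of abundant genes neither needs nor rules out a different content of this tissue sample. In 24 of 43 lists its median lay outside the range of the other 8 libraries, against at most 16 for another library, doxorubicin replicate 3. The ranges used for the other libraries include this one, which can lower their counts.

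Other splits of the same libraries were compared with the real grouping. For each pair of groups the real grouping was the only 1 of 10 splits with as many genes called (4947, 4173 and 262, against a highest other count of 0), and 10 splits are too few for a share under 0.05. For gene lists 5, 2 and 6 of 10 splits called as many lists as the real one (11, 17 and 6, against highest others of 20, 17 and 17). Every other split of a pair leaves part of the group difference between its sides and puts the rest into the spread. Gene calls are thus unlikely in these splits while list calls remain possible. How many lists correlation between genes alone would call is not known. Over 100 drawn splits of all 9 libraries, 1 called as many genes among 3 groups as the real one (5122, highest other 3611) and 1 as many reversed genes (3101, highest other 2770), and it was the real one both times. Each split was given its highest reversed count with each group taken in turn as the middle one. The splits with 2770, 2698 and 2695 reversed genes kept the 3 doxorubicin libraries together and mixed vehicle with formononetin libraries. Random assignment of all 9 libraries to groups is argued against for both counts. The reversed count mostly reflects that the doxorubicin libraries stood apart, and hardly depends on how vehicle and formononetin libraries were grouped.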
